A study of Drosophila melanogaster with 19 samples.

How the data were processed

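The material was RNA from heads of the fruit fly *Drosophila melanogaster* and from S2 cells, a cultured *Drosophila* line of embryonic origin. The flies were wild-type Canton-S or carried C4, an allele of the X-linked gene for the large subunit of RNA polymerase II whose product elongates slowly. The titles give each genotype with the numbers 18 and 29 and with replicates 1 and 2, so that 8 RNA samples of heads form 4 combinations with 2 samples each; the meaning of 18 and 29 is not given in the sources used here, and they are called title numbers. Each RNA sample gave 1 mock-treated library and 1 library treated with RNase R, a 3' to 5' exonuclease that degrades linear RNA and spares closed circles. That makes 8 head groups with 2 libraries per group, 16 head libraries in all. S2 cells gave 1 mock and 1 RNase R library, and 1 further library from wild-type heads kept the strand of the RNA, for a total of 19 libraries.

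Per the labels' protocol, ribosomal RNA was depleted with Ribominus, RNase R was used at 3 units per microgram for 15 min at 37 °C, and libraries were made with the TruSeq RNA kit. Per the submitters' processing notes, CASAVA and Bowtie were run and the genome build was dm3. No versions, junction caller, thresholds or gene annotation are stated in those notes. The deposited values are read counts: whole numbers of reads per back-splice junction, the join between the end of a downstream stretch and the start of an upstream one that a circular RNA carries. The deposited tables give 1 row per junction with its position, strand, a host gene where there is one, and the count of each library. In the head replicate tables and the S2 table every row's counts sum to the row's total, and the stranded table gives 1 count per row. The smallest total is 2 reads in each of the 4 tables. A junction seen once in a whole table is therefore not listed, and a library without listed reads at a junction was taken as 0. All coordinates are dm3, counted from 1.

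Sequencing depth is not part of these tables. The only library size is the sum of listed back-splice reads, so a change in a junction is relative to the other back-splice reads of that library, and counts are displayed as reads per 10000 listed back-splice reads. Totals were 800 to 3427 reads in the 8 mock head libraries and 4871 to 20254 in the 8 RNase R head libraries. At this depth most junctions in a mock library rest on few reads: in replicate 1 of slow18, 314 of the 423 junctions with reads had 1 read. The counts come from amplified libraries without molecular identifiers, so intervals and lower limits cover counting error only.

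The replicate tables were joined on exact chromosome, start, end and strand, and junctions listed in both were tested. Junctions with at least 10 reads over the fitted libraries and reads in at least 2 of them entered each fit. Tests used edgeR 4.0.16 (limma 3.58.1, R 4.3.3): the quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05, two-sided. The SE beside an edgeR log2 fold change is its absolute value divided by the square root of the F statistic. It therefore restates the test and is no separate estimate of the error. RNase R was compared with mock with the RNA sample as a block. The genotypes were compared with the title number as a factor and the title numbers with the genotype as a factor, in mock and in RNase R libraries separately. Interactions of genotype with title number (mock) and with treatment were tested as well. The replicate numbers were not shown to pair libraries, so a replicate block is an alternative. Nothing in the labels says that replicates 1 and 2 came from separate flies, so p-values measure the spread between these samples, which may be technical.

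The plan fixed before the data were examined named TMM factors without saying over which junctions. A simulation of unchanged junctions with the depths of these libraries showed that TMM over all tested junctions gave 70 false calls of 1400 junctions for RNase R against mock, all of them higher, and TMM with singleton pairing gave 38. TMM over the 100 most abundant tested junctions, TMM over junctions with reads in every library, RLE and library totals alone gave 0. In mock libraries compared by title number, the TMM versions over top junctions, over all junctions and with singleton pairing each gave 1 false call of 259, and the other 3 scalings gave 0. TMM over the 100 most abundant junctions was therefore taken as the main scaling. It was chosen out of 6 scalings after the simulation and with the real counts in view, and values under the other scalings stand beside it. In simulations with known changes and a dispersion of 0.04 among 1368 junctions, the RNase R comparison recovered 3.41% of 2-fold and 27.6% of 4-fold changes. The genotype comparison recovered 3.57% and 26.7% among 253 mock junctions and 10.1% and 56.2% among 1257 RNase R junctions. False calls numbered 0, 0 and 2. Most 2-fold changes would therefore be missed in all 3 comparisons, and most 4-fold changes in the RNase R comparison and in the mock genotype comparison.

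Genes were named as the tables name them. Of 1929 symbols, 1248 matched current symbols and 635 matched through synonyms, and current names are given in brackets. Each junction's length was compared with exon annotation of a later build (BDGP6) without converting coordinates: a junction was called single exon, or exon start to exon end, when its length equalled 1 exon or a stretch from an exon start to an exon end of its gene. For 61.7% of 4999 junctions such a stretch was found, against 1.22% to 1.80% when the length was shifted by 1 to 100 bases, which gives the rate of chance matches.

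Named junctions follow a fixed rule: per comparison up to 12 higher and 12 lower with the smallest p among those past the threshold, the 5 with the smallest p where fewer than 3 passed, the 20 most abundant in mock heads, the 10 most abundant in S2 cells, and up to 4 examples per gene list. Any other junction named was chosen after its values were seen. There were 11 lists: synaptic and ion channel genes, axon guidance and adhesion, RNA binding and splicing, circadian clock, transcription factors and chromatin, signalling kinases and GTPase regulators, and markers of eye photoreceptors, glia, muscle, fat body with cuticle, and hemocytes with S2 cells. They were tested over junctions with camera at a preset correlation of 0.01 and again with an estimated one. Their listed name laccase2 matched no symbol, so CG42345 (stw), the laccase 2 gene, is not in the fat body and cuticle list. Junctions of 1 gene are not independent of each other.

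Totals were compared by exact permutation tests, shares carry exact Clopper-Pearson 95% intervals, and a fold against a group without reads was computed against 3 reads over the group. Alternatives were DESeq2 1.42.0, RLE and other scalings, no filter, a filter of 50 reads, the union of the tables, spans of 100 kb or less, blocks, and leaving out each library or RNA sample. Added after the data were seen were the other TMM versions, library totals alone outside the RNase R comparison, and junctions matched to exons. Scripts ran in Python 3.11.15 with scipy 1.17.1. Host-gene mRNA levels and the ratio of circular to linear RNA were not computed, since linear reads are not used here.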

Results

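Back-splice junctions, the marks that circular RNAs leave in RNA sequencing, were counted in fly heads and in S2 cells. Heads came from wild-type Canton-S flies (WT) and from flies with the slow RNA polymerase II allele C4 (slow), each at title numbers 18 and 29 with 2 RNA samples, and every RNA sample was sequenced after mock treatment and after RNase R. The 8 mock head libraries held 800 to 3427 listed back-splice reads (mean 1698 ± 991 SD, n = 8) over 423 to 1092 junctions. The 8 RNase R head libraries held 4871 to 20254 reads (mean 12496 ± 5236 SD, n = 8) over 1293 to 2476 junctions. S2 cells gave 4421 reads in the mock library and 14874 in the RNase R library, and the stranded library from wild-type heads gave 2599. The C4 change lies in the protein and leaves no mark in these counts, so the genotype labels were taken as given.

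Heads contained 4515 listed junctions, and circles from the splicing regulator muscleblind (mbl) led them. One mbl junction, 2R:13162915-13163568 on the plus strand, was the most abundant in all 16 head libraries, with 1136 ± 360 of every 10000 back-splice reads in mock (SD, n = 8). Its length equals 1 partly coding mbl exon. The next was a junction labelled with the muscle and nuclear envelope gene Msp-300, 2L:816665-8042117 with ends 7225453 bases apart, at 337 ± 161. Other junctions with this label lay at 2L:5146993-5148882 and 2L:5168404-5168504, far from both of its ends. Its label therefore does not show that its reads come from Msp-300. Then followed plexA (the semaphorin receptor PlexA), with 230 ± 28.6, the homeobox gene scro, with 204 ± 38.1, CG42345 (stw, which encodes the cuticle enzyme laccase 2), with 198 ± 97.8, and the RNA helicase gene Dbp80, with 148 ± 30.9. Further down came CaMKI (calcium/calmodulin-dependent kinase I), with 103 ± 31.8, the O-GlcNAc transferase gene Ogt (sxc), with 71.4 ± 26.1, and the scaffold gene dlg1, with 59.8 ± 45.3. The tables of replicates 1 and 2 listed 3342 and 3396 junctions. Of all 4515, 2223 stood in both (49.2%) and held 94.7% of head reads. The median distance between ends was 1041 bases (quartiles 348 and 3032), and 31 junctions spanned over 100 kb. By length, 2418 junctions matched a stretch from an exon start to an exon end of their gene and 493 matched a single exon, of which 258 were partly coding, 207 coding and 25 untranslated. No match was found for 1358, and for 246 no host gene was found in the annotation of the later build.

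**Figure D1:**
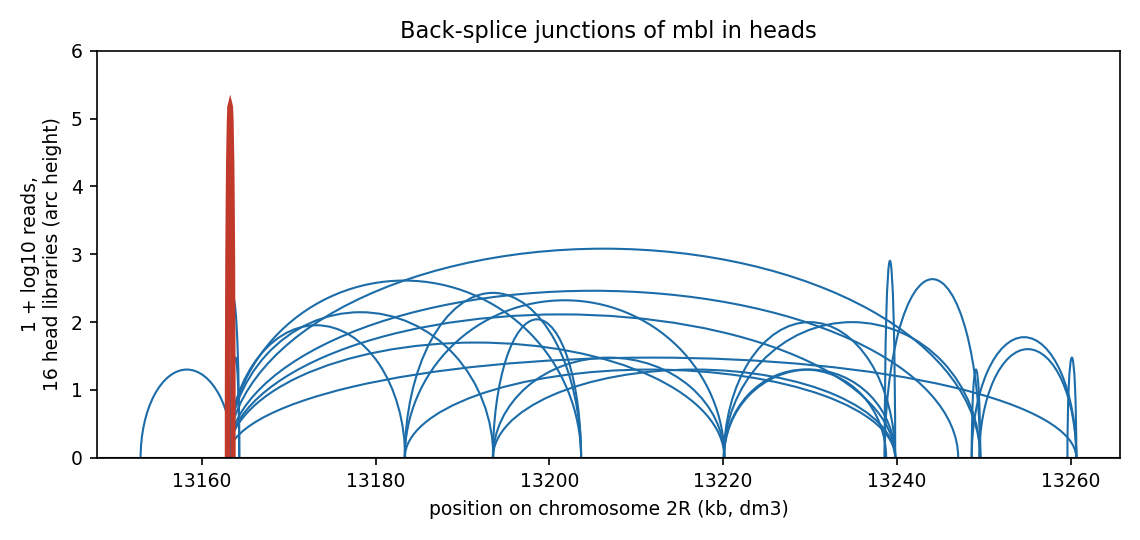
Back-splice junctions of mbl along chromosome 2R (x axis, kb, dm3); each arc joins the ends of 1 of 30 junctions and its height is 1 plus the log10 of its reads summed over the 16 head libraries. The red arc at 2R:13162915-13163568 holds 15526 of the 16027 mbl reads.

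The series treated every RNA sample with RNase R to separate circular from linear RNA, and the total of listed back-splice reads rose in all 8 RNA samples. The ratio of RNase R to mock averaged 2.95 ± 0.64 on the log2 scale (SD, n = 8), a factor of 7.73. It was lowest in replicate 2 of WT29, at 4.64, and highest in replicate 2 of WT18, at 19.1. Samples with a rise numbered 8 of 8, and the exact two-sided sign-flip permutation test gave p = 0.0078125, the smallest p that 8 samples allow. Total reads per library also depend on sequencing depth, which the tables do not state. Mock totals of the 4 slow libraries (mean log2 10.16 ± 0.68 SD) and the 4 WT libraries (10.89 ± 0.88) differed by -0.73 on the log2 scale. That was within the spread of the 8 mock libraries (exact two-sided permutation p = 0.257, smallest possible 0.0286). The permutation ran over all 70 splits without regard to title number, so this spread includes any difference between title numbers. Whether the totals of the genotypes differ within a title number was not tested.

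**Figure D2:**
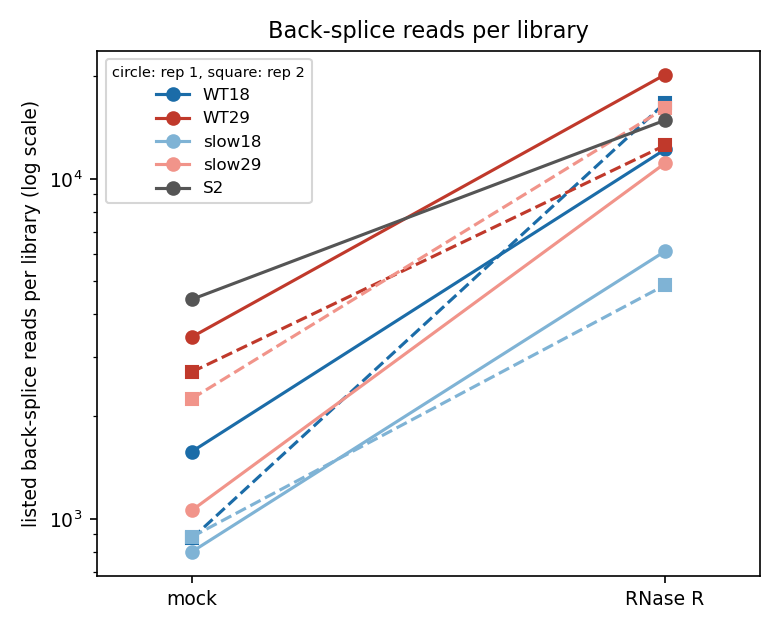
Listed back-splice reads per library (y axis, log scale) after mock and RNase R treatment; lines join the libraries of 1 RNA sample, colours give the group, circles are replicate 1 and squares replicate 2. All 8 head samples and S2 cells rise, from 800 to 3427 up to 4871 to 20254 reads in heads.

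Relative to all back-splice reads, RNase R changed junctions in both directions. The CaMKI junction 4:470550-471135 (plus strand, exon start to exon end) rose from 103 ± 31.8 to 241 ± 48.6 reads per 10000 (SD, n = 8), a log2 fold change of 1.09 ± 0.17 (SE). The single-exon circle of CG42345 (stw), 2R:1311255-1311744, rose from 198 ± 97.8 to 321 ± 165 (log2 fold change 0.64 ± 0.15). On the other side, the Msp-300 junction 2L:816665-8042117 fell from 337 ± 161 to 12.2 ± 8.13 (log2 fold change -4.99 ± 0.18), and junctions of the photoreceptor genes trp (3R:25740455-25740598, a light-activated calcium channel) and ninaE (3R:15712023-15712192, rhodopsin 1) fell, with log2 fold changes of -5.15 ± 0.30 and -5.27 ± 0.41. The plexA junction 4:1042868-1044306 (minus strand, single exon, partly coding) fell from 230 ± 28.6 to 82.3 ± 14.1 (log2 fold change -1.56 ± 0.15).

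By edgeR, 26 junctions were higher and 76 lower of 1354 tested at an adjusted p below 0.05. The edgeR adjusted p was 3.4e-09 for CaMKI, 5.4e-04 for CG42345, 1.6e-157 for Msp-300 and 2.3e-22 for plexA, and each moved its way in 8 of 8 samples. Higher as well were CG6416 (Zasp66, a muscle Z-disc protein), CG13784, the calcium sensor gene Stim, CG34365 (Stacl), CG40084 (uex), the serotonin receptor gene 5-HT2 (5-HT2A), the growth factor gene Pvf3, CG34048 (CG44153) and the endocytosis gene Eps-15, with log2 fold changes from 0.82 to 2.69. The heparan sulfate polymerase gene ttv had no reads in mock and was at least 3.62-fold higher. Lower as well were CG9297, 2 junctions of the titin-like muscle gene bt on chromosome 4, a second trp junction, CG34417, vsg, the calmodulin gene Cam and CG3339, with log2 fold changes from -6.07 to -3.37. The junctions labelled Msp-300, trp, ninaE, CG34417, vsg, Cam and CG3339 matched no exon ends, and raw reads fell for 49 of the 76. Those labelled CG34417 (X:4256493-15005055) and CG3339 (3R:16362926-26526540) also have distant ends, so their host gene is uncertain. The mbl exon circle had 1136 ± 360 and 1397 ± 428 reads per 10000 (log2 fold change 0.23 ± 0.11, edgeR adjusted p = 0.25).

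Photoreceptor markers fell as a group: 8 of 12 junctions were lower and 0 higher (10 lower when adjusted over the list alone; camera adjusted p = 1.8e-09, adjusted p = 0.030 with an estimated correlation). The 4 leading junctions belong to trp and ninaE and start at 3R:25740455 (trp) or 3R:15712023 (ninaE), so they are not independent of each other. As the trp and ninaE junctions named above matched no exon ends, the fall of the list cannot be read as a fall of spliced photoreceptor circles. Fat body and cuticle markers had 2 of 4 junctions lower (2 adjusted over the list alone), Rfabg (apolpp, a lipoprotein of the hemolymph) at -4.53 ± 0.59 and the yolk protein gene Yp2 at -4.22 ± 0.77. Camera gave fat body and cuticle markers adjusted p = 0.0139, or adjusted p = 0.094 with an estimated correlation. Muscle markers had 4 of 9 junctions lower (4 adjusted over the list alone), 2 of them in bt, 1 in the myosin light chain gene Mlc2 (-5.57 ± 0.89) and 1 in the myosin heavy chain gene Mhc (-2.71 ± 0.55). The muscle list missed the threshold with the RNA sample as block (camera adjusted p = 0.0527) and passed it without that block (adjusted p = 8.6e-04). With the block, camera gave muscle markers adjusted p = 0.135 with an estimated correlation. No other list passed. RNA binding and splicing genes had 0 of 56 junctions higher and 2 lower, in pum and a long mbl junction (0 adjusted over the list alone). Synaptic and ion channel genes had 1 higher, in sif, and 2 lower, in Caps, of 88 (3 adjusted over the list alone). Axon guidance genes had 2 lower of 32 (3 adjusted over the list alone, 1 of them higher), plexA among them, and transcription factors 2 lower of 28, in E2f and pan (2 adjusted over the list alone). The signalling, circadian clock, glial and hemocyte lists had 0 of 19, 4, 1 and 3 called (1 hemocyte junction, in Ppn, when adjusted over the list alone). Over all lists of this paragraph from RNA binding on, camera adjusted p ranged from 0.393 for transcription factors to 0.915 for axon guidance, RNA binding and synaptic genes, and the glial list with 1 junction was not tested. Camera compares a list with all other junctions, whose median log2 fold change was 0.38. The axon guidance, circadian clock, RNA binding and signalling lists have positive medians and means beside a downward test, and the transcription factor list has a median of -0.01 and a mean of 0.02. The means of the axon guidance (0.55) and RNA binding (0.42) lists lie above 0.38, so that median alone does not account for their downward tests.

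The number of calls depends on the scaling and the filter. TMM over all tested junctions gave 302 (249 higher, 53 lower, median log2 fold change 1.12), RLE 119 (50 and 69, median 0.56), DESeq2 269 (238 and 31), a filter of 50 reads 63 (38 and 25), exon-matched junctions alone 56 (31 and 25), no scaling at all 1213 (1192 and 21), and leaving out replicate 1 of WT29 64; the plexA fall lost its call with DESeq2 (-0.20) and became 1.44 without any scaling.

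**Figure D3:**
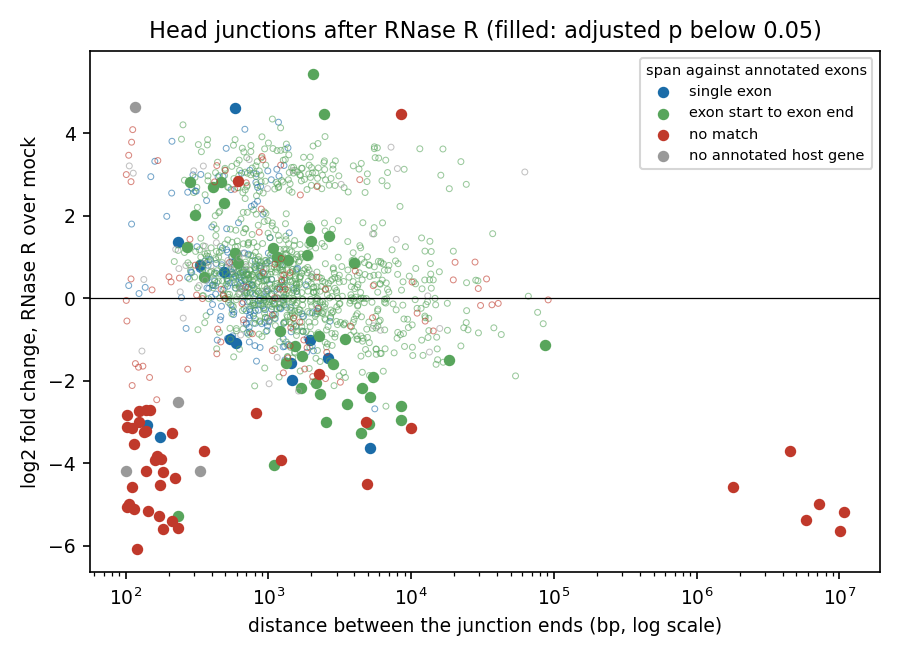
Log2 fold change of 1354 head junctions after RNase R (y axis, relative to all back-splice reads) against the distance between their ends (x axis, bp, log scale); colours show whether that distance matches annotated exons and filled points have an edgeR adjusted p below 0.05. Of the 76 lower junctions 41 matched no exon ends, and 6 spanned over 100 kb.

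The series set slow against WT to ask whether polymerase speed bears on circles, and no junction of mock heads passed the test for it. The smallest p belonged to CG9339 (sky, a synaptic Rab regulator; 2L:20881987-20882464), with 15.7 ± 3.34 reads per 10000 in WT and none in slow (SD, n = 4; at least 2.72-fold lower), and to the adhesion gene Nrg (X:8425558-8426497), with 15.6 ± 7.01 and none (at least 2.52-fold lower). CG17622 (wake) had 10.7 ± 12.3 in WT and none in slow, and the N-cadherin gene CadN 14.3 ± 17.3 and 3.12 ± 6.25. The bt junction 4:758362-758535 had 61.2 ± 31.3 and 125 ± 72.2, and it was among the junctions lower after RNase R. The mbl exon circle had a log2 difference of 0.49 ± 0.25.

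Of 230 junctions tested with edgeR, 0 passed, and 16 had an unadjusted p below 0.05 (DESeq2: 0 passed and 4); the adjusted p was 0.111 for each of the 5 named and 0.617 for mbl. Photoreceptor markers had 0 of 9 junctions called, with trp at 0.88 ± 0.35 and 1.64 ± 0.56 (1 passed when adjusted over the list alone). Muscle markers had 0 of 5, led by the bt junction at 1.07 ± 0.35 (1 when adjusted over the list alone). Camera placed both above the other junctions (adjusted p = 0.0175 each), and with an estimated correlation the adjusted p was 0.179 for each. The trp, ninaE and bt junctions leading these lists were among those lower after RNase R, and those of trp and ninaE matched no exon ends. These shifts can therefore not be read as shifts of photoreceptor or muscle circles. Axon guidance and adhesion genes had 0 of 6 called (2 adjusted over the list alone), led by Nrg and CadN, and lay below the others by camera (adjusted p = 0.0454), which was lost with an estimated correlation (adjusted p = 0.251) and with a replicate block (adjusted p = 0.0529). The RNA binding, signalling, synaptic and transcription factor lists had 0 called, with camera adjusted p from 0.329 to 0.633, and RNA binding genes had a negative median beside a positive mean and an upward test. The 2 fat body junctions, in Yp2 and Rfabg, were not tested as a list. A filter of 50 reads called 2 of 30 junctions, bt among them, and 1 junction passed without replicate 1 of slow18 (CadN) or of slow29 (bt).

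In RNase R libraries, with 4871 to 20254 reads each, slow heads differed from WT. The beat-Vc junction 3R:8578140-8580512 (minus strand, a neuronal immunoglobulin gene) fell from 20.1 ± 3.11 to 0.94 ± 0.70 reads per 10000 (SD, n = 4), a log2 fold change of -4.02 ± 0.51 (SE). CG31304 (CG42788; 3R:10926459-10927926) had no reads in WT and 10.2 ± 5.95 in slow, at least 21.5-fold higher. The mbl exon circle rose from 1128 ± 182 to 1667 ± 448 (log2 fold change 0.58 ± 0.15). A dlg1 junction on X (11275889-11277145) fell from 23.9 ± 5.46 to 4.75 ± 1.08 (-2.38 ± 0.36), and junctions of the translational repressor gene pum (3R:5043709-5044485) and the synaptic GTPase exchange factor gene sif (3L:5697025-5699673) fell as well (log2 fold changes -1.78 ± 0.35 and -1.52 ± 0.32).

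By edgeR, 11 junctions were higher and 25 lower of 1221 tested. The edgeR adjusted p was 4.4e-12 for beat-Vc, 1.6e-11 for CG31304, 2.9e-08 for dlg1 and 0.0093 for mbl, and each moved its way in 4 of 4 pairs of libraries with the same title number and replicate number. Higher as well were the spinophilin gene Spn, CG11319 (Dpp10), the kainate receptor gene CG9935 (Ekar), the sex-determination gene dsx, CG33111, an unnamed junction at 3L:4987077-4988264, the transcription factor gene seq and Ald, with log2 fold changes from 1.09 to 3.09, and the chromatin kinase gene JIL-1, without reads in WT and at least 5.92-fold higher. JIL-1 rests on replicate 2 of slow29, with 8 reads there and 1 in each other slow library. It falls below the filter without replicate 2 of slow29. So does Ald, with 7 and 8 reads in slow29 and none in slow18. Lower as well were spri, CG41087, CG34377, CG31163 (SKIP), Ccn, toc, the polarity gene sdt and the hypoxia factor gene sima, with log2 fold changes from -2.85 to -1.01. No list passed camera (adjusted p from 0.371 to 0.896). Synaptic genes had 3 of 78 junctions lower, in dlg1, sif and the calcium channel gene cac (3 adjusted over the list alone), axon guidance genes 1 of 30, in trio (1 adjusted over the list alone), and RNA binding genes 1 higher, mbl, and 1 lower, pum, of 52 (4 adjusted over the list alone, 3 of them higher). The photoreceptor, muscle, transcription factor, signalling, circadian clock, fat body and hemocyte lists had 0 of 7, 8, 27, 18, 3, 1 and 2 called. Medians, means and tests differed in sign for the photoreceptor, circadian clock, synaptic and RNA binding lists. DESeq2 called 16, and 18 passed without replicate 2 of slow29. RLE gave 17 higher and 19 lower, as the median log2 fold change moved from -0.12 to -0.01. The mbl rise lost its call with TMM over all junctions (0.50), with singleton pairing (0.53) and without replicate 2 of WT18 (0.55).

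**Figure D4:**
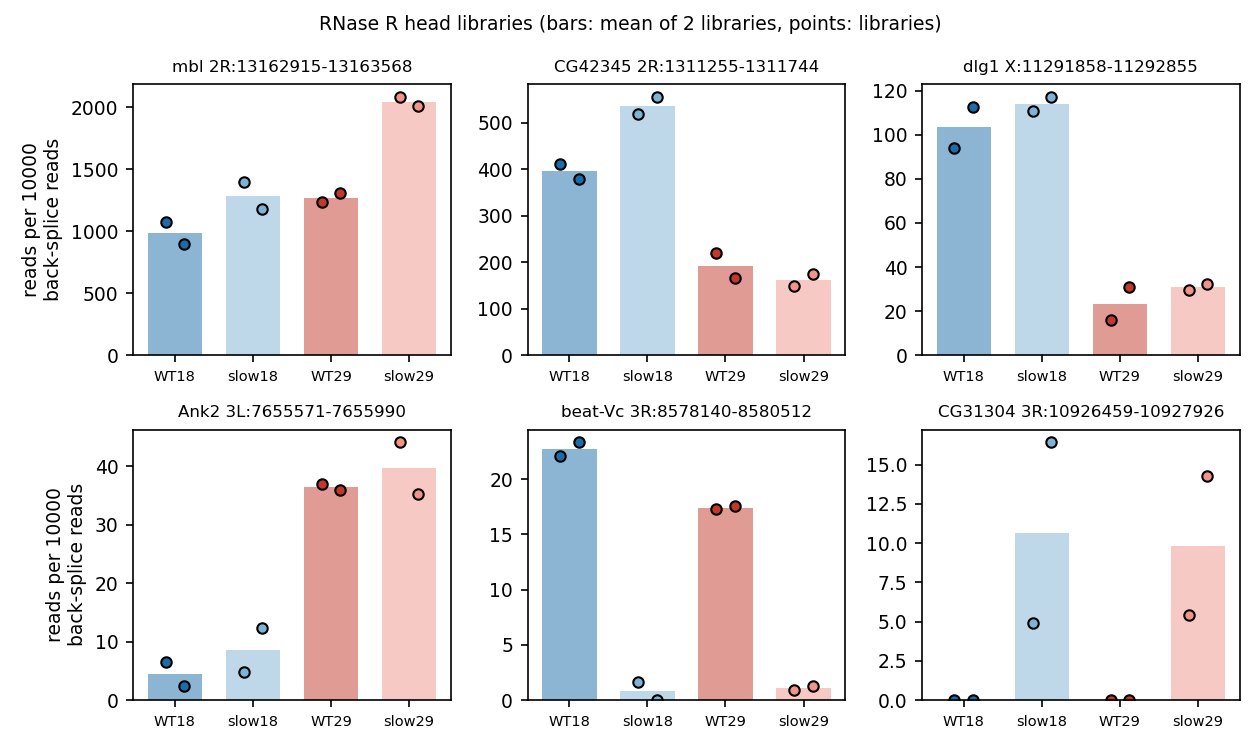
Reads per 10000 back-splice reads (y axis, from 0) of 6 junctions in the RNase R head libraries; bars are means of 2 libraries per group and points are the libraries. The mbl circle lies higher in slow than in WT at both title numbers, dlg1 X:11291858-11292855 and CG42345 lie lower at 29 than at 18, and CG31304 has reads in slow libraries only.

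Title numbers 29 and 18 separated the heads more than the genotypes did by count of calls, a difference that was not tested. In RNase R libraries the dlg1 junction X:11291858-11292855 fell from 109 ± 9.97 reads per 10000 at 18 to 27.2 ± 7.67 at 29 (SD, n = 4), a log2 fold change of -2.08 ± 0.20 (SE), and in mock from 101 ± 14.8 to 19.1 ± 11.9 (-2.36 ± 0.44). The laccase 2 circle CG42345 fell from 466 ± 83.8 to 177 ± 30.4 (-1.42 ± 0.16), and in mock from 279 to 117 (-1.14 ± 0.30). The basigin gene Bsg (2L:8105692-8107880) fell from 36.8 ± 13.3 to 3.96 ± 1.13 (-3.31 ± 0.32) and the receptor phosphatase gene Lar (2L:19714889-19715953) from 23.7 ± 8.81 to 1.07 ± 1.03 (-4.34 ± 0.44). Ank2 (ankyrin 2; 3L:7655571-7655990, single exon) rose to 38.1 ± 4.07 at 29 (2.69 ± 0.32), Stim (X:15830832-15831064) by 1.78 ± 0.26 and the metabotropic glutamate receptor gene mGluRA (mGluR; 4:958958-959743) by 2.04 ± 0.32.

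With edgeR, 70 junctions were higher and 102 lower at 29 of 1221 tested in RNase R libraries. The edgeR adjusted p was 2.6e-21 for dlg1 and Bsg, 5.2e-20 for Lar, 2.1e-15 for CG42345 and 5.7e-15 for Ank2, and each moved its way in 4 of 4 pairs. Higher as well were CG17684, the vesicle priming gene Caps (Cadps), CG30089, CG1358 (HisT), CG41099, the LIM homeobox gene ap, KrT95D and Parp (Parp1), with log2 fold changes from 1.42 to 2.73, and an unnamed junction at 3R:7576892-7577007 without reads at 18, at least 9.53-fold higher. Lower as well were an unnamed junction at 2R:6681630-6681989, Gef64C (RhoGEF64C), bt, the kinase gene smi35A (Dyrk2), the stress response factor gene cnc, CG4266 (Isha) and CG17304 (btsz), with log2 fold changes from -2.58 to -1.42, and Pino, without reads at 29 and at least 13-fold lower. Among mock libraries 5 junctions were higher and 6 lower of 230. Higher were mGluRA (2.88 ± 0.78), CG31619 (nolo, 2.72 ± 0.79), seq (at least 2.48-fold), Stim (at least 2.34-fold) and CG40084 (2RHet:3169315-3169621, 2.47 ± 0.81). Lower were dlg1, CG42345, bt (-1.28 ± 0.35), CG34417 (-1.77 ± 0.50), Bsg (-2.54 ± 0.75) and the splicing regulator gene ps (-1.80 ± 0.58; edgeR adjusted p from 2.4e-05 for dlg1 to 0.0476 for CG40084). The mbl exon circle rose by 0.47 ± 0.15 in RNase R libraries (edgeR adjusted p = 0.0216) and had 0.63 ± 0.26 in mock (adjusted p = 0.122).

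No gene list passed camera for the title numbers, with adjusted p from 0.102 to 0.911 in RNase R libraries and from 0.234 to 0.866 in mock. After RNase R, synaptic and ion channel genes had 6 junctions higher and 5 lower of 78 (13 adjusted over the list alone, 7 of them higher), and the 6 higher were mGluRA and 5 junctions of 1 gene, Caps, with dlg1 among the lower. RNA binding genes had 7 higher and 4 lower of 52 (12 adjusted over the list alone, 7 of them higher), with aret (1.39 ± 0.44) and Sxl (3.09 ± 0.81) among the higher and cpo (-1.11 ± 0.23) and ps (-1.02 ± 0.28) among the lower. Axon guidance genes had 4 lower of 30 and 0 higher, in Lar, Eph, CG5467 and CG14351 (4 adjusted over the list alone). Muscle markers had 3 lower and 1 higher of 8, in bt and the tropomyosin gene Tm1 (4 adjusted over the list alone), and camera gave adjusted p = 0.102. The insulin receptor gene InR was lower (-4.08) and Haspin higher (0.79 ± 0.21) among 18 signalling junctions (2 adjusted over the list alone). The transcription factor list had tai lower (-1.09 ± 0.27) of 27, and the fat body list its 1 junction, in Yp3, lower (-3.47 ± 0.87), each also 1 over the list alone. The photoreceptor, circadian clock and hemocyte lists had 0 of 7, 3 and 2 called (1 hemocyte junction, in Ppn, when adjusted over the list alone). Mock libraries had 1 muscle junction lower of 5 (bt), 1 RNA binding junction lower of 12 (ps; 4 adjusted over the list alone, 2 of them higher) and 1 synaptic junction each way of 12 (mGluRA, dlg1). Medians, means and tests differed in sign for the photoreceptor and RNA binding lists after RNase R and for axon guidance genes in mock. The balance of directions moved with scaling. TMM over all junctions gave 90 higher and 74 lower, RLE 92 and 76 (median log2 fold change 0.05 against -0.13) and DESeq2 63 and 34. A filter of 50 reads gave 114 calls, and 104 passed without replicate 2 of WT18. In mock, DESeq2 and the fit without a filter each called 1 junction (dlg1), a filter of 50 reads called 4, and 2 to 6 passed when any 1 library other than replicate 1 of slow18 was left out.

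**Figure D5:**
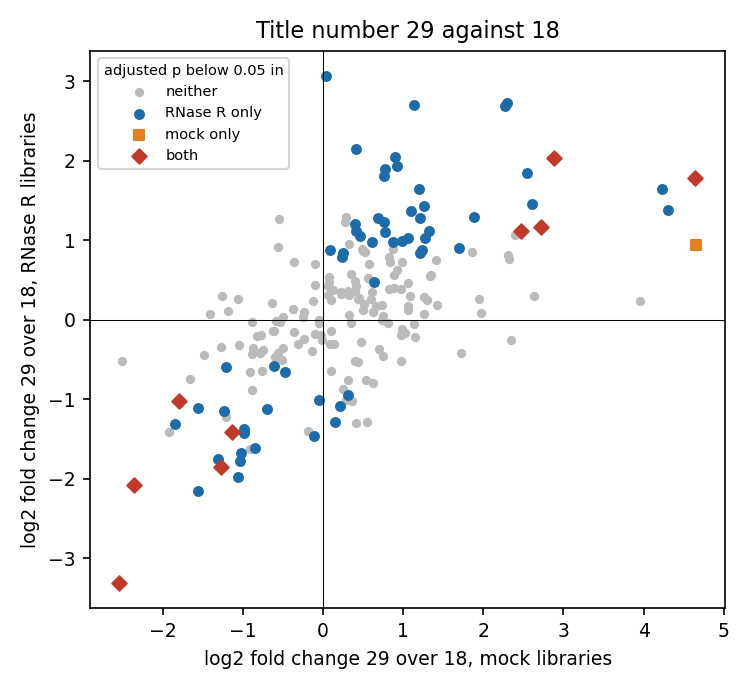
Log2 fold change of title number 29 over 18 in mock (x axis) and RNase R (y axis) head libraries for junctions tested in both; blue circles pass edgeR's adjusted p below 0.05 in RNase R only, the orange square in mock only, and red diamonds in both. Of 66 junctions called after RNase R and tested in mock, 63 lie on the same side of 0 in mock.

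Differences between effects were tested next, and no junction passed. For genotype by title number in mock, the smallest p belonged to CadN, a 5-HT2 exon circle (3R:448231-449346), Dbp80 (3LHet:2423418-2423807), CG34377 and Asph, with interaction log2 values from -8.55 ± 3.26 to 5.58 ± 2.36 and an edgeR adjusted p of 0.888 each. For genotype by treatment they were Nrg (7.22 ± 2.10, adjusted p = 0.804), Pde1c, eIF-4B, Galpha49B (Galphaq) and dlg1, and the other 4 had an edgeR adjusted p of 1. Of 230 and 1354 junctions, 0 passed in each, with 8 and 22 at an unadjusted p below 0.05 (DESeq2: 0 passed in each, with 0 and 9). These fitted values rest on junctions with few or no reads in some groups. The interaction of genotype and title number in RNase R libraries was not tested.

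S2 cells carried a different set of abundant junctions, led by CG17646, an ABC transporter family gene. Its 32 junctions rose from 979 reads (22.1% of S2 back-splice reads) to 4505 (30.3%) after RNase R, against 0.167% of head reads in 6 junctions. The leading one, 2L:1741660-1742260, had 295 and 1935 reads, a share 1.95 times as large after RNase R (95% interval 1.72 to 2.21). CG11299 (Sesn, a stress-response gene) at 2R:19609733-19610398 had 160 and 845 reads, CG33232 (Svil) 73 and 491, and CG4266 (Isha) 37 and 272. The single-exon luna junction 2R:6987037-6987619 had 386 and 264 reads, and its share fell to 0.203 times (0.173 to 0.238). The long Msp-300 junction had 357 and 125 (0.104 times, 0.0842 to 0.128). The mbl exon circle had 10 and 56 reads, 37.6 per 10000 after RNase R, against 1367 per 10000 head reads. No reads of the dlg1 circle X:11291858-11292855, CG32245 or the bt and trp junctions were listed in S2 cells.

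Of 1280 junctions listed in S2 cells, 940 had more reads after RNase R (73.4%, 95% interval 70.9 to 75.8), and 59.8% rose by more than the ratio of the library totals, 3.36. Both shares count the 593 junctions of S2 cells without mock reads, which rise by construction in the deeper RNase R library. With 1 library per treatment there is no replicate check, and these values compare 2 libraries. Junctions with at least 10 reads rose in 85.0% of 200 cases, and in 62.0% by more than the ratio of the totals. At the same coordinates, 39.8% of S2 junctions (509 of 1280; 37.1 to 42.5) were listed in heads, and 62.4% of those with at least 5 reads were.

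The stranded library from wild-type heads listed 447 junctions, led again by the mbl exon circle with 447 reads (17.2%, 95% interval 15.8 to 18.7). CG42345 followed with 68 reads, CG40084 with 44, plexA with 41 and bt with 33, and the long Msp-300, the trp and the CG34417 junctions had none listed. Of its junctions 91.7% (410 of 447; 88.8 to 94.1) stood in the unstranded head tables at the same coordinates, and 97.7% of those with at least 5 reads did. All 410 carried the same strand there, and they held 96.5% of its reads.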

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

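The tests of exon matching and of scaling for junctions that fell after RNase R, of mock libraries for the title numbers, of the X chromosome for the genotypes, the count of host genes whose calls share 1 direction and the gaps between junctions of a gene were chosen after the results were seen; the others were fixed earlier. Junctions were examined for opposite effects in every library, which 4 of 132 checks showed, fewer than a chance of 5.56% per check would give, so the following are descriptions only. Dbp80 at 3LHet:2423418-2423807 in mock libraries met this for both factors: its means were 20.9 and 9.92 reads per 10000 in WT18 and WT29 and 0 and 18.3 in slow18 and slow29, a difference of differences of 29.3. The edgeR interaction test gave Dbp80 an adjusted p of 0.888 (unadjusted p 0.0193). CG1358 at 2R:3489937-3493749 in RNase R libraries was lower in slow than in WT at 18 (3.48 and 6.16) and higher at 29 (28.99 and 17.996), a difference of differences of 13.7 that was not tested. The dlg1 junction X:11275889-11277145 in RNase R libraries was higher at 29 than at 18 in WT (27.3 and 20.4) and lower in slow (3.97 and 5.53), a difference of differences of -8.44 that was not tested either. In 7 measures of totals, ratios, mbl share and exon-matched share, Dixon's test set no library or RNA sample apart from the 8 that were compared.

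The fall of 76 junctions after RNase R, led by the long junction labelled Msp-300 and by junctions of trp and ninaE, is the first pattern. Scaling is argued against as the whole cause, since between 53 and 76 of these junctions were still lower with edgeR under each of 5 other scalings, but DESeq2 with its own size factors called 31 of them lower and 1 higher (68 had a log2 fold change below 0 and 16 no adjusted p), and 21 were lower without any scaling, which leaves the ratio of totals in. Of the fallen junctions with an annotated gene, 43.8% (32 of 73) had a length that matched exon ends, against 92.3% (1133 of 1227) of the others (two-sided Fisher's exact p = 4.37e-24), and all 6 tested junctions over 100 kb fell. A candidate explanation is that many of these reads come from linear molecules joined in library making or mapping, not from spliced circles; it leaves open the 32 matched ones, such as plexA, and no biological explanation was tested. With treatment labels swapped within RNA samples, 1 of 100 assignments gave as many calls, the real one (102, highest other 71). This argues against chance but does not exclude it.

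The title-number difference in RNase R libraries, seen in dlg1, CG42345, Bsg, Lar and Ank2, is the second pattern, and library depth is argued against as its cause: with replicate 2 of WT left out, where the library of 18 was the deeper one, 89.1% of 119 called junctions had the same sign in that left-out pair (95% interval 82.0 to 94.1). RNase R treatment is argued against as well for the called junctions that could be tested in mock. Of these, 95.5% (63 of 66) showed the same sign there and 9 were also called there, although mock and RNase R libraries share RNA samples. For the rest of the 172 calls, Lar among them, mock reads were too few for a test. Of 25 genes with several calls 7 had both directions, where 3 had been set beforehand as the bar. Under the main scaling this argues against a change of the whole host gene as the only cause for the 6 with both junctions on 1 strand. Of the 7, 5 kept both directions with library totals alone, and 3 each with RLE, TMM over all junctions and TMM over junctions in every library. Singleton pairing kept 2 and missed the bar, so the argument depends on scaling. Gaps within the 6 were 1.86 ± 0.42 (ps) to 5.79 ± 1.45 (pum, with SE) on the log2 scale, but these pairs were picked for opposite calls. The pum junction that rose was itself among those lower after RNase R, so its reads need not come from a circle. A change of the host gene stays open for Msp-300, with its calls on opposite strands, for 18 genes with calls in 1 direction and for 110 with a single call, since linear reads would decide it. Only the real split gave as many calls, 1 of 34 in RNase R libraries (172 calls, highest other 16) and 1 of 34 in mock (11, highest other 1). This argues against chance without excluding it, as 1 of 34 is the smallest share possible and not all splits were balanced over genotype. What the title numbers stand for stays open as the biological difference.

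The genotype difference in RNase R libraries, seen in beat-Vc, CG31304, dlg1 and mbl, is the third pattern, and RNase R treatment is argued against as its cause for the called junctions that could be tested in mock, with 89.5% of them (17 of 19; 95% interval 66.9 to 98.7) showing the same sign there. None of the 19 passed in mock, and mock and RNase R libraries share RNA samples. For the rest of the 36 calls, beat-Vc and CG31304 among them, mock reads were too few for a test. In RNase R libraries 1 of 34 splits, the real one, gave as many calls (36, highest other 2), which argues against chance. It does not exclude chance, since 1 of 34 is the smallest share possible. Not all splits were balanced over the title number, and the 2 samples per group may be technical replicates. In mock and for genotype by treatment the real count is 0, so the 34 of 34 and 35 of 35 splits with as many calls say nothing about chance. Strain background near the X-linked mutation cannot be told apart from the polymerase: 11.1% of the called junctions (4 of 36; interval 3.11 to 26.1) and 16.2% of the others lay on X (Fisher's exact p = 0.498), and variants on other chromosomes were not tested. The count takes X as a whole, so it cannot detect an excess close to the mutation. The 4 called X junctions lay in dlg1, spri, cac and sdt, and their distance from the mutation was not tested. Slower polymerase and strain background may both contribute, and the design holds no second strain to separate them.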

How the results depend on the processing

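The TMM versions over all junctions, with singleton pairing and over junctions in every library, the exon-matched set, and library totals alone outside the RNase R comparison were added after the results were seen; the other alternatives were fixed earlier. For RNase R against mock (102 calls), DESeq2 gave 269, a filter of 50 reads 63, no scaling 1213, TMM over all junctions 302, singleton pairing 279 and exon-matched junctions 56, and leaving out 1 RNA sample 64 to 93, lowest without replicate 1 of WT29; plexA turned to 1.44 without scaling, which leaves the depth ratio in. For genotype in mock (0), a filter of 50 reads gave 2, and 1 library left out 0 to 1. For genotype after RNase R (36), DESeq2 gave 16, and 1 library left out 18 to 40, lowest without replicate 2 of slow29, where 7 named junctions lost their call. For title numbers in mock (11), DESeq2 gave 1, no filter 1, a filter of 50 reads 4, and 1 library left out 2 to 10. For title numbers after RNase R (172), DESeq2 gave 97, a filter of 50 reads 114, and 1 library left out 104 to 184, lowest without replicate 2 of WT18; none of the 24 named junctions lost its call with any 1 library left out. Interactions gave 0 under every alternative run, 0 to 0 with 1 library left out. Fewer junctions enter under the filter of 50 reads and the exon match; for the other differences the cause was not tested. A lone library left in a group is assumed to vary like the others. The log2 ratio of totals ranged from 2.77 to 3.06 and the genotype difference of totals from -1.10 to -0.44 with 1 sample left out. The share of S2 junctions that rose was 85.0% with at least 10 reads (73.4% for all); with at least 5 reads the overlap with heads was 62.4% for S2 (39.8%) and 97.7% for the stranded library (91.7%). A replicate block gave 39 calls for genotype and 165 for title number after RNase R, 0 and 10 in mock, and p = 0.278 for the genotype totals (exact permutation within replicates); without the sample block RNase R gave 106. Correlations of residuals between libraries with the same replicate number ranged from -0.05 to 0.22 in mock and from -0.04 to 0.05 after RNase R. With fewer reads, the mock comparisons could test 230 junctions against 1221 after RNase R. Replicates of WT29 mock differed by no more than counting error (chi-square ratio 1.06), against 1.21 to 2.84 in the other groups.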

Other observations

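The test of gene length for chromosome 4 was written before its result was seen. The descriptions of host genes and of genes with junctions called in both directions were chosen after their values were seen. Junctions were spread over 1689 host genes in heads, 867 of them with 1 junction and 57 with 10 or more. Ppn (papilin, an extracellular matrix protein) had the most, 37, with 5 mock and 152 RNase R reads in all, ahead of the potassium channel gene slo with 33, mbl with 30, Msp-300, pan and Rfabg (apolpp) with 28 each, sif with 26, and Caps (Cadps), CG17108 and the sodium channel gene para with 24 each. Of these 10 genes, slo held 0.212% ± 0.246 of mock reads and para 0.292% ± 0.128, against 11.8% ± 3.72 for mbl (SD, n = 8). One mbl junction held 96.9% of the gene's 16027 reads. Of 119 genes with at least 5 junctions and 100 reads, 70 had over 50% of their reads in 1 junction. Of 4375 junctions with a gene, 51.7% shared a start or an end with another junction of the heads.

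Under the scaling used, 7 genes had junctions called in opposite directions between title numbers 29 and 18 after RNase R (edgeR, SE of each fold change given). Under the other scalings 2 (TMM with singleton pairing) to 5 (library totals alone) of these 7 genes kept calls in both directions. In ps, the exon circle 3R:5257751-5258561 fell by 1.02 ± 0.28 on the log2 scale and 3R:5270766-5272219 rose by 0.84 ± 0.31. In Tm1, 3R:11110335-11111076 fell by 1.78 ± 0.52 and 3R:11120835-11121266 rose by 1.58 ± 0.44. The RNA-binding gene bl (2R:16483062-16483319 at -1.53 ± 0.53, 2R:16483062-16486199 at 0.88 ± 0.30) and MESK2 (2R:17397623-17399682 at 2.30 ± 0.76, 2R:17398372-17399682 at -1.14 ± 0.40) did so with a shared start or end. Parp had 3RHet:1964215-1964748 at 1.42 ± 0.29 and 3RHet:2018688-2019257 at -0.66 ± 0.22, and pum 3R:4944891-4947147 at 3.07 ± 1.05 and 3R:5057796-5060386 at -2.73 ± 1.01. The pum junction that rose at 29 was itself lower after RNase R than in mock, so its reads need not come from a circle. The Msp-300 pair lies on opposite strands. The gap between the junctions of a gene hardly depends on scaling by construction, since a scaling factor shifts both alike, so its stability is no check of the opposite calls. For Parp the gap was 2.08 ± 0.37 (SE, junctions taken as independent) and 2.06 to 2.08 under 5 other scalings, and for pum 5.79 ± 1.45 and 5.63 to 5.81. These pairs were picked for their opposite calls.

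Chromosome 4, the small heterochromatin-rich autosome that carries plexA, CaMKI, bt, pan, Caps and mGluRA, had a high share of host genes: 45 of its 80 protein-coding genes (56.3%) hosted a head junction, against 11.2% elsewhere (odds ratio 10.2, two-sided Fisher's exact p = 2.48e-22). The share was 12.8% on X and 10.05% to 11.5% on the arms of chromosomes 2 and 3. Host genes were longer than others (median 16817 and 1909 bases). Over classes of gene length the common odds ratio fell to 3.89 (95% interval 2.19 to 6.99, exact conditional p = 8.83e-07). Gene length may therefore account for part of the excess, and differences between the classes did not account for all of it. Genes within a class can still differ in length, so the test cannot exclude gene length as the whole cause. Expression level and intron content were not tested.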
